A study of Mus musculus with 12 samples.

How the data were processed

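RNA was measured in 12 sorted cell samples of mouse pancreas at E17.5, in 3 groups of 4. Per the labels, RNA was extracted with an RNeasy mini plus kit and libraries were made with a SMARTER mRNA-Seq kit, and the replicates come from different mothers. Per the submitters' processing notes, STAR 2.5.2b and DRAGEN were used, and the genome builds GRCm38 (mm10) and GRCm39 (mm39) are named. Which tool and build made which table, and how reads shared between genes were divided, is not given in the sources used here. Per the file headers, the authors deposited estimated counts and TPM per gene for each library in a table on each build, and these were taken as the authors' own values. The deposited TPM were not used for any test. The estimated counts deposited on GRCm39 were used, because that table holds the reporter sequences EGFP, IRES and mRFP1 and the mitochondrial genes, and because the highest counts in the mm10 table looked capped. This choice was made after the tables were opened and before any test. A further deposited sheet, a filtered copy of the mm10 table, was not used here.

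Estimated counts were rounded to whole numbers, which changed no library total by more than 0.000286%. Library totals ranged from 16216967 to 38545756, and intervals and spreads cover sampling and replicate error of these libraries only. Genes with low counts were removed with filterByExpr, which left 17230 of 55417, and TMM factors ranged from 0.732 to 0.81 in N, from 1.12 to 1.18 in A and from 1.1 to 1.14 in B. All 12 libraries were fitted together by group with edgeR 4.0.16 (quasi-likelihood test, glmQLFit and glmQLFTest) in R 4.3.3, with a common biological coefficient of variation of 0.305, and p values were adjusted by the Benjamini-Hochberg method at 0.05. Standard errors of log2 changes were derived from the quasi-likelihood F statistic. No pair of libraries in a group agreed within sampling noise, so each was counted as its own replicate.

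Gene lists, 24 in number, covered alpha, beta and other islet cell genes, endocrine progenitors and transcription factors, secretory granules, channels, cell cycle, guidance and adhesion, Notch, unfolded protein response, respiratory chain and glycolysis, the acinar, ductal, mesenchymal, endothelial, immune, erythroid, Schwann and neural and mesothelial cell types, and dissociation stress, mitochondrially encoded and ribosomal protein genes. Some genes stand in more than 1 list. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and also with an estimated correlation and with fry. Fry's directional p tests whether the genes of a list move on balance one way and does not compare the list with other genes. The groups, comparisons, lists, tests, the rule for named genes and most of the alternatives below were set before the data were examined.

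The rule named, for each comparison, Gcg and the reporter sequences, the 8 highest and 8 lowest genes by log2 change (4 and 4 for B against N) among genes with adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between groups, and for each list of main interest the first gene and the 3 members with the smallest p (the first gene alone for B against N), and for each other list the member with the smallest p. It named 77 genes for B against A, 73 for A against N and 31 for B against N, of which 58, 68 and 29 were called, and not all are printed; 1 gene is not reported here. Shares of counts were compared with exact two-sided permutation tests over 70 splits.

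The replicate numbers were checked as pairs. The labels say that replicates come from different mothers and that each pancreas preparation was sorted into the 3 groups, and the Y-linked genes showed one pattern per number in all 3 groups, at 112 to 156 CPM in replicate 1 and 0.191 to 0.488 CPM in replicate 3. Deviations from the group means correlated between same-numbered A and B libraries at 0.04, 0.16, 0.13 and 0.23. The numbers were taken as pairs on the labels and the Y-linked genes before any paired fit was compared, and the block was run as an alternative.

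Other alternatives were RLE and upper quartile factors, DESeq2 1.42.0, no filter, a filter of 10 counts in 8 libraries, fits of only the groups compared, a test against a fold change over 2, the mm10 table, and each library left out in turn. After the data were seen, a fit without the A and B libraries numbered 3 and a fit with library totals alone and no normalisation factors were added. The tests were checked on simulated counts with known changes. For B against A, in a run of 16865 genes, 2.99% of genes changed by 0.5 on the log2 scale, 49.3% of those changed by 1 and 87.9% of those changed by 2 were recovered, and 2 of 16665 unchanged genes were called. For A against N the shares were 2.94%, 45.5% and 81.8%, and for genes that changed at both steps 35 of 100 were recovered and 0 others were counted.

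Genes with near-identical copies, such as Ins1 and Ins2, Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, and the Amy and Serpina1 genes, are uncertain as single genes, since the counting could split their reads. The use of strand in counting is not given in the sources used here, so overlapping and antisense genes are uncertain as well.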

Results

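RNA sequencing was carried out on cells sorted from pancreata of Gcg-Timer mouse embryos at E17.5. Gcg-Timer mice carry a fluorescent reporter tied to Gcg, the glucagon gene, and per the labels cells with mostly green signal are newly generated alpha cells and cells with green and red signal are more differentiated alpha cells. Each pancreas preparation was sorted into non-alpha cells (group N), green dominant cells (group A) and green and red cells (group B), with 4 libraries in each group and 12 in all. Total counts per library ranged from 32114292 to 38545756 in N, from 18168677 to 25873635 in A and from 16216967 to 24259218 in B. Between 22746 and 23809 genes were detected in N libraries, between 19445 and 22038 in A libraries and between 20180 and 21383 in B libraries. After a filter on low counts, 17230 of 55417 genes were tested. Levels are normalised read counts (CPM, scaled to the library size), given as mean ± SD with n = 4 per group, and changes are on the log2 scale with their standard error (SE).

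**Figure D1:**
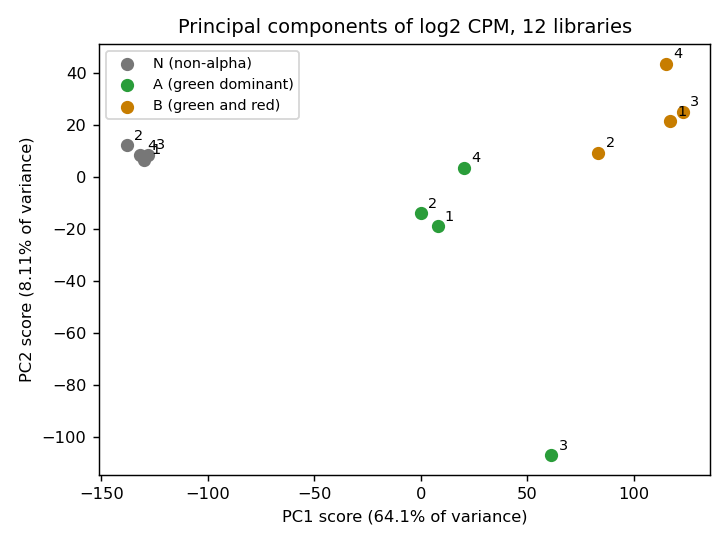
Scores of the 12 libraries on the first component (x axis, 64.1% of the variance) and the next component (y axis, 8.11%) of log2 CPM, with the replicate number beside each point. The N libraries lie between -138 and -128 on the x axis, the A libraries between 0.227 and 61.3 and the B libraries between 83.4 and 123, and A replicate 3 stands apart at -107 on the y axis.

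The comparison of B with A addressed how more differentiated alpha cells differ from newly generated ones. Gcg (ENSMUSG00000000394.16, chromosome 2, 62304874 to 62313994 in GRCm39) was higher in B, at 37300 ± 7190 CPM against 15400 ± 4430 CPM in A (log2 change 1.28, SE 0.26, edgeR adjusted p = 0.00613). It stood at 102 ± 30.9 CPM in N. Gcg took 4.2% ± 0.86 of all counts in B and 1.76% ± 0.478 in A (exact two-sided permutation test, n = 4 per group, p = 0.0286, the smallest p that the 70 splits allow). The reporter sequences rose by more, with log2 changes of 2.19 (SE 0.29) for EGFP, 2.19 (SE 0.32) for mRFP1 and 2.13 (SE 0.31) for IRES. The ratio of EGFP to Gcg counts was 0.0902 ± 0.0194 in B and 0.0481 ± 0.0149 in A, a difference that did not pass an exact two-sided permutation test (n = 4 per group, p = 0.0571). This ratio and the Gcg share of counts were each higher in B in all 4 replicate pairs. That number of pairs allows no permutation p under 0.125. The ratio of mRFP1 to EGFP counts was 1.29 ± 0.0176 in B and 1.29 ± 0.0301 in A (exact two-sided permutation test, n = 4 per group, p = 0.714).

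In all, 797 genes were higher and 1571 lower in B than in A, 2368 together, of which 189 and 1193 changed by more than 2-fold. Of the 1571 lower genes, 1034 were also lower in A than in N, as most mesenchymal and endothelial markers were. Genes of other cell types were not set apart in these counts. With the hypothesis of a fold change over 2 tested directly, 404 genes passed. The count was 1506 without B replicate 1 and 1523 without A replicate 2. Of the 24 gene lists, camera called 4 higher and 11 lower in B. None of these 15 was called by camera with an estimated correlation, and fry called 13 lists. Of the 35 splits of the 8 libraries, 5 called as many lists. The lists are therefore described by the number of their members that passed the test.

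Among 18 measured alpha cell identity genes, 7 rose, 2 fell and 9 were not called in B against A, and adjusted over the list alone 10 rose and 2 fell (camera adjusted p = 0.00106, and adjusted p = 0.294 with an estimated correlation). Slc38a5, an amino acid transporter, rose from 3620 ± 637 to 7370 ± 535 CPM (log2 change 1.03, SE 0.19, edgeR adjusted p = 0.00374). Etv1, a transcription factor, rose from 229 ± 45.3 to 394 ± 25.1 CPM. Fxyd5 fell from 4.4 ± 2.49 to 0.804 ± 0.169 CPM and was highest in N, at 15.8 ± 3.48 CPM. Outside the lists, Fbp1, a gluconeogenic enzyme, rose from 25.3 ± 8.44 to 115 ± 22.7 CPM (log2 change 2.18, SE 0.25). Bco1, a carotenoid oxygenase, rose from 22 ± 7.54 to 77 ± 11.4 CPM and Mapk4 from 11.1 ± 1.72 to 33.5 ± 7.98 CPM. Ankrd6 and Tmem179 rose by 1.61 (SE 0.24) and 1.79 (SE 0.35) on the log2 scale.

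**Figure D2:**
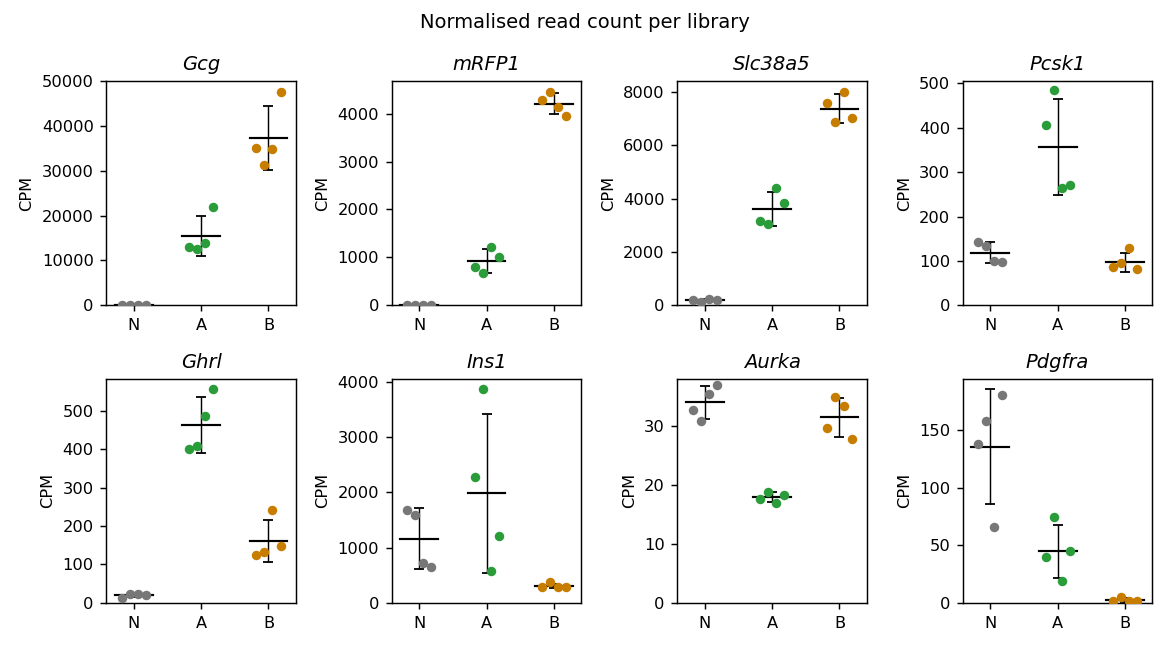
Normalised read count (y axis, CPM) of 8 genes in the N, A and B libraries, with 4 points per group, the mean as a line and the SD as a bar. Gcg, mRFP1 and Slc38a5 step up from N to A to B, Pcsk1 and Ghrl are highest in A, Aurka is lowest in A, Pdgfra steps down, and the A libraries spread widely for Ins1.

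Some hormone genes of other islet cells were lower in B than in A. Of 12 measured delta, PP and epsilon cell genes, 4 fell, 0 rose and 8 were not called, and 7 fell adjusted over the list alone (camera adjusted p = 0.00112, and adjusted p = 0.237 with an estimated correlation). Ghrl, which encodes ghrelin, fell from 462 ± 73.5 to 161 ± 53.8 CPM (log2 change -1.52, SE 0.24, edgeR adjusted p = 0.0015). Ppy, which encodes pancreatic polypeptide, fell from 311 ± 86.4 to 131 ± 44.1 CPM and Pyy, which encodes peptide YY, from 3580 ± 427 to 2390 ± 242 CPM. Sst, the somatostatin gene, stood at 246 ± 125 CPM in A and 138 ± 47.3 CPM in B (edgeR adjusted p = 0.116). Of 17 measured beta cell genes, 9 fell, 0 rose and 8 were not called, and 10 fell adjusted over the list alone (camera adjusted p = 2.22e-05, and adjusted p = 0.267 with an estimated correlation). Ins1, an insulin gene, fell from 1980 ± 1440 to 310 ± 41.2 CPM (log2 change -2.68, SE 0.49, edgeR adjusted p = 0.00354), with wide spread among the A libraries. Mafa, a beta cell transcription factor, fell from 21.5 ± 14.4 to 3.36 ± 0.67 CPM, and Nnat and Sytl4 fell by 2.7 and 2.4 on the log2 scale.

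Of 30 measured secretory granule genes, 6 rose, 1 fell and 23 were not called in B against A, and adjusted over the list alone 6 rose and 2 fell (camera adjusted p = 0.00179, and adjusted p = 0.353 with an estimated correlation). Vgf, a granule protein, rose from 12.9 ± 2.9 to 37.5 ± 3.7 CPM, and Ptprn, a granule membrane protein, from 81.5 ± 17.7 to 182 ± 37 CPM. Pcsk1, a prohormone convertase, fell from 356 ± 108 to 97.4 ± 21.5 CPM (log2 change -1.87, SE 0.22, edgeR adjusted p = 0.000464). Of 19 measured channel and transporter genes, 1 rose and 4 fell, among them Slc2a2, a glucose transporter, which went from 57.9 ± 39.1 to 10.4 ± 5.49 CPM. Slc2a2, Pcsk1 and Ins1 were each higher in A replicates 1 and 2 than in A replicates 3 and 4, and the same held for the N replicates. Beta cell genes took 1.35% ± 0.724 of counts in A and 0.518% ± 0.032 in B. The channel and transporter list was not called (camera adjusted p = 0.998), and its median of 0.11 and mean of -0.2 differed in sign. Of 15 pan-endocrine transcription factors, 0 rose and 1, Mnx1, fell, from 6.97 ± 0.961 to 3.11 ± 0.693 CPM (camera adjusted p = 0.359). Of 17 endocrine progenitor genes, 0 rose and 2 fell, among them Amotl2 (log2 change -0.77, SE 0.12), and the list was not called (camera adjusted p = 0.953; median 0.05 and mean -0.02). Neurog3, the endocrine progenitor transcription factor, stood at 35 ± 22 CPM in A and 16.1 ± 10.8 CPM in B (edgeR adjusted p = 0.182), and was called lower in B when the replicate number was added to the fit as a block.

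Of 32 measured cell cycle genes, 10 rose, 0 fell and 22 were not called in B against A, and 18 rose adjusted over the list alone (camera adjusted p = 7.5e-09, and adjusted p = 0.267 with an estimated correlation). With upper quartile factors, or with no factors, 7 rose and 0 fell. Aurka, a mitotic kinase, rose from 17.9 ± 0.852 to 31.5 ± 3.26 CPM (log2 change 0.82, SE 0.11, edgeR adjusted p = 0.000885). Mcm7 and Mcm2, subunits of the replicative helicase, rose by 0.55 (SE 0.1) and 0.63 (SE 0.13). Mki67 stood at 19.2 ± 6.68 CPM in A and 25 ± 4.09 CPM in B (edgeR adjusted p = 0.238).

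Of 22 measured endoplasmic reticulum chaperone and unfolded protein response genes, 7 fell, 0 rose and 15 were not called in B against A, and 10 fell adjusted over the list alone (camera adjusted p = 0.000187, and adjusted p = 0.353 with an estimated correlation). Hspa5, the chaperone BiP, stood at 2600 ± 307 CPM in A and 1930 ± 218 CPM in B (edgeR adjusted p = 0.0833). Of 17 glycolysis genes, 4 fell and 0 rose, and adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.0761). Hk1, a hexokinase, fell from 13.7 ± 1.47 to 3.91 ± 1.54 CPM and Ldha, lactate dehydrogenase A, from 321 ± 23.8 to 149 ± 68.7 CPM. Both were highest in N, at 47 ± 1.76 and 1060 ± 153 CPM. Of 35 nuclear respiratory chain genes 0 were called by edgeR and 0 by DESeq2, 1 was higher at an unadjusted p under 0.05, and the list was not called (camera adjusted p = 0.164). Beside these groups, acinar genes took 6.1% ± 1.24 of counts in A and 3.66% ± 1.59 in B (exact two-sided permutation test, n = 4 per group, p = 0.0857), and less in B in all 4 replicate pairs.

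Most mesenchymal, endothelial, immune and mesothelial markers were lower in B than in A. Of 16 mesenchymal genes, 14 fell and 2 were not called, and all 16 fell adjusted over the list alone (camera adjusted p = 3.3e-12, and adjusted p = 0.237 with an estimated correlation). Pdgfra, a receptor of mesenchymal cells, went from 136 ± 49.8 CPM in N to 44.7 ± 22.9 CPM in A and 2.87 ± 1.76 CPM in B (log2 change from A to B -3.95, SE 0.48, edgeR adjusted p = 0.000501). Lox, a collagen crosslinking enzyme, fell from 85.5 ± 39.9 to 8.08 ± 5.2 CPM, and the collagen gene Col14a1, Vcan, Mrc2, Pcdh18, S100a6 and Kcnj8 were also among the genes that fell most. Of 12 endothelial genes 11 fell (camera adjusted p = 6.9e-08, and adjusted p = 0.237 with an estimated correlation), and adjusted over the list alone 12 fell. Of 14 immune genes 8 fell (camera adjusted p = 2.22e-05, and adjusted p = 0.267 with an estimated correlation), and adjusted over the list alone 12 fell. Of 8 mesothelial genes 5 fell (camera adjusted p = 0.00112, and adjusted p = 0.237 with an estimated correlation), and adjusted over the list alone 6 fell. Of 15 ductal genes 6 fell and 1 rose (camera adjusted p = 0.00127, and adjusted p = 0.3 with an estimated correlation), and adjusted over the list alone 10 fell and 1 rose. Of 22 acinar genes 1 fell (camera adjusted p = 3.86e-05, and adjusted p = 0.353 with an estimated correlation), and adjusted over the list alone 10 fell. The mesenchymal share of counts was 48.9% of its N level in A and 6.57% in B, and the endothelial share 48.2% and 10.9%. Of 11 erythroid genes 0 were called by edgeR and 1 fell by DESeq2, with 4 lower and 1 higher at an unadjusted p under 0.05 (camera adjusted p = 0.289). Their share of counts was 1.11% of its N level in A and 0.438% in B.

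**Figure D3:**
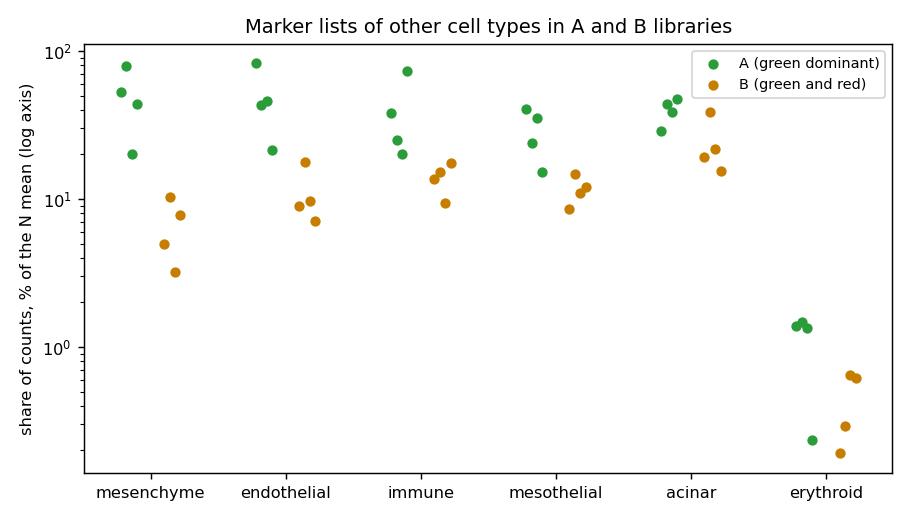
Share of counts taken by 6 marker lists in each A and B library, as a percent of the mean share in the N libraries (y axis, log scale), with 4 points per group and list. The mesenchymal share of the A libraries lies between 20.2 and 79.2% of N and that of the B libraries between 3.23 and 10.3%, while the erythroid share is at most 1.47% in every A and B library.

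Some Notch pathway and guidance genes fell beside those markers. Of 16 Notch pathway genes, 5 fell, 0 rose and 11 were not called in B against A, and 7 fell adjusted over the list alone (camera adjusted p = 0.00143, and adjusted p = 0.237 with an estimated correlation). Notch3 fell from 11.8 ± 3.86 to 1.82 ± 0.493 CPM, Jag1, a Notch ligand, from 36.2 ± 7.53 to 12.5 ± 4.84 CPM, and Heyl from 14.3 ± 4.77 to 3.76 ± 2.69 CPM. Notch1 stood at 37.5 ± 11.8 CPM in A and 40.2 ± 7.54 CPM in B. Of 30 guidance and adhesion genes, 7 fell, 1 rose and 22 were not called, and 13 fell and 3 rose adjusted over the list alone (camera adjusted p = 0.00479, and adjusted p = 0.3 with an estimated correlation). Slit2, a guidance ligand, fell from 45.4 ± 22.7 to 5.2 ± 2.73 CPM, Nrp1 from 88 ± 23.6 to 17.7 ± 6.09 CPM and Cxcl12, a chemokine, from 108 ± 45.9 to 22.9 ± 12.5 CPM. Notch3, Jag1, Heyl, Slit2, Nrp1 and Cxcl12 were each highest in N, and the mesenchymal share of counts was 0.767% ± 0.382 in A and 0.103% ± 0.049 in B.

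Of 12 Schwann and neural genes, 1 rose and 1 fell in B against A (camera adjusted p = 0.123). The gene that rose was Gfra3, a receptor of the GDNF family, which went from 11.5 ± 1.15 CPM in N to 71.8 ± 4.99 CPM in A and 181 ± 13.2 CPM in B (log2 change from A to B 1.34, SE 0.1, edgeR adjusted p = 0.000105). Of 18 dissociation stress genes 1 rose and 1 fell (camera adjusted p = 0.998), with a median of 0.04 and a mean of -0.07, and the median was -0.01 with upper quartile factors. Of 13 mitochondrially encoded genes 0 were called by edgeR, by DESeq2 or at an unadjusted p under 0.05, and their list was called higher in B (median 0.36, camera adjusted p = 0.0335, and adjusted p = 0.673 with an estimated correlation). Of 30 ribosomal protein genes 0 were called by edgeR, by DESeq2 or at an unadjusted p under 0.05 (camera adjusted p = 0.998).

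**Figure D4:**
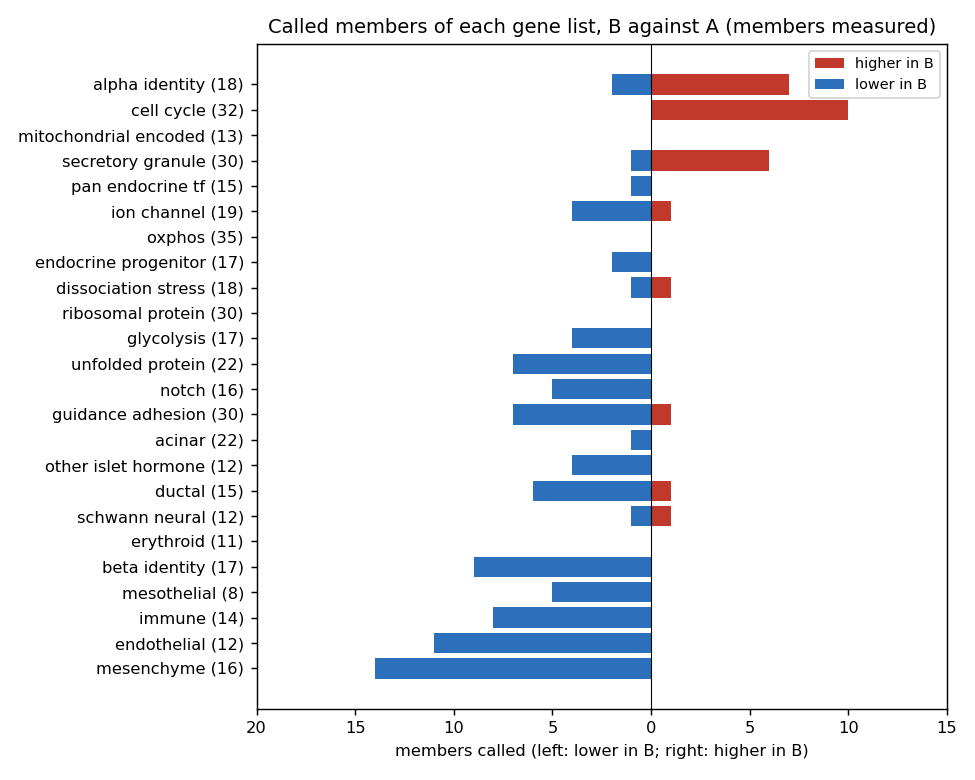
Number of members of each of 24 gene lists (y axis, with the number measured) that were called higher in B (red, to the right) or lower in B (blue, to the left) than in A. Cell cycle genes have the most members called higher, 10 of 32, and mesenchymal genes the most called lower, 14 of 16.

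The comparison of A with N set newly generated alpha cells against the remaining pancreatic cells. Gcg was higher in A by 7.24 on the log2 scale (SE 0.33, edgeR adjusted p = 4.84e-09), EGFP by 8.42 (SE 0.4) and mRFP1 by 8.45 (SE 0.43). The cells were sorted on this reporter of Gcg, so these rises follow from the gates and only check the sort. Irx1 and Irx2, transcription factors of alpha cells, were higher by 7.14 (SE 0.41) and 6.7 (SE 0.22), and Ndst4 and Nxph1 by 6.29 (SE 0.36) and 5.89 (SE 0.18). Red blood cell genes were among those that fell most, with Hbb-bs, a beta globin gene, at 67700 ± 37900 CPM in N and 456 ± 244 CPM in A. Hba-a1, an alpha globin gene, stood at 53300 ± 28600 and 423 ± 226 CPM and Alas2, the erythroid haem synthesis enzyme, at 2020 ± 1050 and 14.5 ± 9.12 CPM. In all, 4099 genes were higher and 3664 lower in A than in N, 7763 together, and 1566 passed when a fold change over 2 was tested directly. Directions in this comparison are relative to the typical gene. With library totals alone and no factors, a setting chosen after the data were seen, the median of all genes moved by 0.57 and 8243 genes were higher and 1386 lower. Camera called 7 lists higher and 11 lower, of which 3 were called with an estimated correlation. Of the 35 splits of the 8 libraries, 2 called as many lists.

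Most alpha cell, granule and channel genes and pan-endocrine transcription factors were higher in A than in N. Of 18 alpha cell identity genes 15 rose and 2 fell (camera adjusted p = 9.05e-12, and adjusted p = 0.049 with an estimated correlation), of 30 secretory granule genes 29 rose and 0 fell (adjusted p = 2.43e-19 and 0.0388), and of 19 channel and transporter genes 15 rose and 2 fell (adjusted p = 1.08e-07 and 0.0106). In this comparison the counts printed were the same adjusted over the list alone unless given. Pcsk2, the convertase that releases glucagon, rose from 141 ± 20.7 to 2300 ± 340 CPM, Scg3, a granule protein, from 59.4 ± 12.5 to 485 ± 30.5 CPM. Abcc8, the sulfonylurea receptor of the ATP-sensitive potassium channel, rose from 125 ± 15.8 to 1590 ± 248 CPM. Of 15 pan-endocrine transcription factors 14 rose, among them Isl1 (log2 change 3.88, SE 0.2) and Pax6 (3.2, SE 0.17), with camera adjusted p = 1.06e-08, and adjusted p = 0.11 with an estimated correlation. Of 17 endocrine progenitor genes 9 rose and 2 fell (camera adjusted p = 0.0134, and adjusted p = 0.398 with an estimated correlation). With no factors 12 of them rose and 1 fell, with a median of 1 against 0.42. Fev rose from 5.94 ± 2.54 to 53.1 ± 11.8 CPM, while Neurog3 stood at 35 ± 16.9 CPM in N and 35 ± 22 CPM in A. Of 17 beta cell genes 8 rose and 1 fell (camera adjusted p = 0.0176, and adjusted p = 0.462 with an estimated correlation). Iapp, which encodes amylin, rose from 878 ± 529 to 3380 ± 686 CPM. Ins1, at 1160 ± 548 CPM in N and 1980 ± 1440 CPM in A, was not called (edgeR adjusted p = 0.191), but was called higher with no factors. With no factors the beta cell list had 14 members higher and a median of 1.27 against 0.7, and its camera call ended (adjusted p = 0.15). Of 12 other islet hormone genes 5 rose and 3 fell (camera adjusted p = 0.0149, and adjusted p = 0.156 with an estimated correlation), with Ghrl at 19.4 ± 5.07 CPM in N and 462 ± 73.5 CPM in A, and with no factors 6 rose and 0 fell, the median was 1.5 against 0.93, and the camera call ended (adjusted p = 0.176).

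Members of several broad lists were lower in A than in N. Of 32 cell cycle genes 30 fell and 0 rose (camera adjusted p = 4.96e-11, and adjusted p = 0.156 with an estimated correlation), with Mki67 at 61.9 ± 2.61 CPM in N and 19.2 ± 6.68 CPM in A. All 30 ribosomal protein genes fell (camera adjusted p = 4.96e-11, and adjusted p = 0.254 with an estimated correlation), with Rps2 at 224 ± 22.5 and 116 ± 14.2 CPM. With no factors these falls were smaller, with 13 of the cell cycle genes lower and 2 higher (median -0.35 against -0.92) and 6 of the ribosomal protein genes lower (median -0.24 against -0.81). Of 16 Notch pathway genes 11 fell and 2 rose (camera adjusted p = 0.00904, and adjusted p = 0.159 with an estimated correlation), among them Hes1, a Notch target, from 42.4 ± 2.35 to 17.3 ± 4.49 CPM, and with no factors 6 fell and 2 rose. Of 22 unfolded protein genes 9 fell and 0 rose (camera adjusted p = 0.00937, and adjusted p = 0.487 with an estimated correlation), but with no factors the direction turned, with 2 lower and 6 higher, and the list was not called (adjusted p = 0.209). Acinar genes took 15.4% ± 3.48 of counts in N and 6.1% ± 1.24 in A (exact two-sided permutation test, n = 4 per group, p = 0.0286, the smallest the splits allow). The acinar share was lower in A in all 4 replicate pairs, a number of pairs that allows no permutation p under 0.125. Without A replicate 1, 2, 3 or 4 that difference was -8.73, -9.51, -9.23 or -9.67 points, each with a permutation p of 0.0571. Every A library still stayed below every N library, at 7.25% or less against 10.5% or more. Erythroid genes took 14.5% ± 7.81 of counts in N and 0.161% ± 0.085 in A.

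Of the other cell type lists in A against N, 21 of 22 acinar genes fell (camera adjusted p = 3.39e-09, and adjusted p = 0.216 with an estimated correlation) and 15 of 16 mesenchymal genes (adjusted p = 0.0001 and 0.398). The same 2 tests gave 10 of 12 endothelial genes lower (adjusted p = 0.00298 and 0.398) and 7 of 14 immune genes (adjusted p = 0.00131 and 0.371), and adjusted over the list alone 12 and 8 fell. With no factors, 8 mesenchymal, 4 endothelial and 6 immune genes were lower. The 2 tests also gave 8 of 8 mesothelial genes lower (adjusted p = 0.000406 and 0.11) and 11 of 11 erythroid genes (adjusted p = 8e-09 and 0.11). Of 15 ductal genes 9 fell and 2 rose (camera adjusted p = 0.0296, and adjusted p = 0.46 with an estimated correlation), and adjusted over the list alone 12 fell and 2 rose. The rise of Krt7, a keratin, from 123 ± 18.7 to 394 ± 47.2 CPM had the smallest p of that list. The guidance, respiratory chain, glycolysis, Schwann and neural, dissociation stress and mitochondrially encoded lists were not called, with adjusted p from 0.0619 to 0.688. With no factors, the median turned from -0.4 to 0.17 for glycolysis, from -0.43 to 0.16 for guidance and from -0.1 to 0.47 for the respiratory chain, where 26 of 35 genes were then higher. It also turned from -0.38 to 0.19 for dissociation stress, where 6 genes were then higher and 3 lower, and from -0.36 to 0.21 for mitochondrially encoded genes.

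The comparison of B with N set more differentiated alpha cells against non-alpha cells, and 5118 genes were higher and 5257 lower in B, 10375 together. With a fold change over 2 tested directly, 4484 passed. With no factors the median of all genes moved by 0.54, and 8263 genes were higher and 3407 lower. Gcg was higher in B by 8.52 on the log2 scale (SE 0.35, edgeR adjusted p = 1.11e-09), which again follows from the sort on its reporter. Hbb-bs fell by 8.53, and Hba-a1 fell by 8.35. Of the endocrine groups, 15 of 18 alpha cell identity genes rose (camera adjusted p = 1.8e-08, and adjusted p = 0.12 with an estimated correlation), 29 of 30 secretory granule genes (adjusted p = 1.61e-14 and 0.0891) and 12 of 15 pan-endocrine transcription factors (adjusted p = 8.27e-06 and 0.196). Chga, chromogranin A, stood at 295 ± 66.6 CPM in N and 1860 ± 365 CPM in B. Of 19 channel and transporter genes 15 rose and 4 fell (camera adjusted p = 6.15e-05, and adjusted p = 0.0628 with an estimated correlation). Of 17 endocrine progenitor genes 9 rose and 3 fell (camera adjusted p = 0.0393, and adjusted p = 0.44 with an estimated correlation). With no factors 13 of them rose and 2 fell, with a median of 0.96 against 0.42. Of 12 other islet hormone genes 5 rose and 4 fell (camera adjusted p = 0.235). Of 17 beta cell genes 5 rose and 8 fell (camera adjusted p = 0.495), with Ins1 lower in B than in N by 1.9 on the log2 scale (SE 0.48), at 310 ± 41.2 against 1160 ± 548 CPM. Of 22 unfolded protein genes 20 fell (camera adjusted p = 0.000136, and adjusted p = 0.374 with an estimated correlation), and with no factors 7 fell and 1 rose. Of 17 glycolysis genes 10 fell and 2 rose (camera adjusted p = 0.0393, and adjusted p = 0.459 with an estimated correlation), and with no factors 5 fell and 5 rose (adjusted p = 0.132). Hk1 stood at 47 ± 1.76 CPM in N and 3.91 ± 1.54 CPM in B. Of 32 cell cycle genes 19 fell and 2 rose, and 20 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.00202, and adjusted p = 0.44 with an estimated correlation), but with no factors the median turned from -0.48 to 0.06 (adjusted p = 0.186). Of 16 Notch genes 11 fell and 2 rose (camera adjusted p = 0.00363, and adjusted p = 0.196 with an estimated correlation), or 9 and 3 with no factors, and 29 of 30 ribosomal protein genes fell (adjusted p = 1.13e-07 and 0.374), with all 30 adjusted over the list alone and 15 with no factors. Of the other cell type lists, 21 of 22 acinar genes fell (camera adjusted p = 2.52e-08, and adjusted p = 0.243 with an estimated correlation), all 16 mesenchymal (adjusted p = 1.13e-07 and 0.243), all 12 endothelial (adjusted p = 2.27e-05 and 0.243) and all 14 immune genes (adjusted p = 3.91e-05 and 0.243). All 11 erythroid (camera adjusted p = 1.26e-06, and adjusted p = 0.196 with an estimated correlation), all 8 mesothelial (adjusted p = 0.00019 and 0.132) and 12 of 15 ductal genes fell (adjusted p = 0.00845 and 0.376). Camera called 5 lists higher and 12 lower, and 0 of these 17 with an estimated correlation. Of the 35 splits of the 8 libraries, 9 called as many lists.

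Across the sequence from N to A to B, 552 genes rose at both steps and 1034 fell at both, 1586 together. Independent lists of the same sizes would share 190 and 334 genes. In 20 simulations of unchanged groups there were 0 of either kind, but these hold no changed genes. They therefore cannot show the overlap expected when many genes change at each step. The mesenchymal share of counts also stepped down, to 48.9% of its N level in A and 6.57% in B. Such markers were not set apart from the genes that fell. Because the A libraries enter both steps with opposite sign, they were also split, with 2 used for each step, and the 6 such splits gave from 51 to 542 genes that rose at both steps and from 47 to 814 that fell at both. The total was 1012 without A replicate 1, 979 without A replicate 2 and 1031 without B replicate 1. With no factors it was 1117. A smaller number of genes turned in A, with 40 highest there and 65 lowest there, fewer than the 374 and 169 that independent lists would share, and with the A libraries split in the same way there were from 4 to 14 and from 1 to 11. Of the 65 lowest in A, 8 were among the 32 measured cell cycle genes, including Aurka, Mcm7, Ccna2 and Kif11, of which Ccna2 and Kif11 were picked out after their values were seen. The genes highest in A included Ghrl, Ppy, Pyy and Pcsk1.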

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

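Among the tests, those on mixture in the proportions of N, on non-erythroid cells mixed alike (over means and in each library), on a lower share of alpha cells, on reporter brightness, on N cells and the cell cycle, and on late against early cell cycle genes were chosen after the result was seen; the others were set before.

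Mesenchymal and endothelial markers were higher in A than in B. N cells mixed into A in the proportions of N are argued against, since mesenchymal genes, as a percent of N, stood at least 14.9 times above erythroid genes in every A library. Without A replicate 3, 27 of the 28 measured members were still lower in B. That replicate had the lowest mesenchymal level of the A libraries, so this test cannot decide on a single deviating library. The levels of single libraries argue against one. The mesenchymal share was at least 20.2% of N in every A library and at most 10.3% in every B library. For the endothelial share these values were 21.5% and 17.9%. Mesenchymal and endothelial cells sorted with A remain open, and the members kept about the ratios they have in N, with an interquartile range of the log2 difference from N of 0.49 or less, which is consistent with whole cells or their RNA being carried over past the reporter gate; a difference named by the design, in how far A cells had differentiated, was not tested for these genes. Carry-over of all non-erythroid N cells alike also remains open. The mean levels of 5 marker lists lay within 1.7 times of each other, which met the criterion set for it. The ductal and the Schwann and neural lists were not among the 5. They stood at 86% and 159% of N in A, against 28.8% for the mesothelial list, so over all non-erythroid lists the criterion was not met. Both hold genes that were higher in A than in N, such as Krt7 and Gfra3. A stricter form of this test was added after the first result. Within single A libraries the 5 lists spread by 2.29 to 4.82 times, which does not settle it.

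Gcg and the reporter sequences were higher in B than in A. Whether a lower share of alpha cells in A was the whole cause cannot be told from the list. The 17 other alpha identity genes rose by a median of 0.39 (interquartile range 0.5) against 1.28 for Gcg. That gap was larger than the interquartile range, which met the criterion written against this cause. The list also holds genes that other cells express, such as Fxyd5, which was highest in N. These would not follow the alpha share. Of the 18 alpha identity genes 7 rose, 2 fell and 9 were not called, with Slc38a5 up by 1.03 (SE 0.19). Sorting on reporter brightness remains open, since EGFP rose relative to Gcg by 0.93 on the log2 scale (SE 0.27), which is consistent with gates that select on the reporter, although the exact permutation p of that ratio was 0.0571 (n = 4 per group). A difference in differentiation, which the design names, also remains open.

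Of 32 cell cycle genes, 30 were called lower in A than in N and 10 lower in A than in B. N cells mixed into B-like cells in the proportions of N are argued against, since 31 of 32 members had an A mean below both other means. That count restates the pattern seen, and carry-over of N cells that cycle less was not tested. The scaling cannot be told apart for the difference between A and B: the median rise was at least 0.35 under the other factors, but these moved the median of all genes by no more than -0.04, and 7 members were called under upper quartile factors. For A against N the size depended on the scaling, since with no factors 13 members fell and 2 rose. Whether the brighter gate took cells late in the cycle cannot be told apart, since 20 late genes rose by 0.07 more than 12 early genes, whose own interquartile range was 0.18, and a difference in proliferation, which was not tested otherwise, stays open too.

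Over all splits, taken without regard to the replicate pairs, the real grouping alone gave as many changed genes. For B against A only 1 of the 35 splits, the real one with 2368 genes, gave as many, and the highest other gave 30; for A against N it was 1 of 35 (7763, highest other 0), for B against N 1 of 35 (10375, highest other 0), and for genes changed at both steps 1 of 100 (1586, highest other 0). With the pairs kept, this cannot exclude chance. Only 8 of the 35 splits part all replicate pairs, too few for a share under 0.05. Among them the highest other counts were 16, 0 and 0. The 100 splits did not keep the pairs. Chance cannot be excluded for the number of lists called, since 5 of 35 splits gave as many for B against A (15, highest other 17), 2 of 35 for A against N (18, highest other 18) and 9 of 35 for B against N (17, highest other 18).

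Single libraries whose gap to the nearest of the others took most of their group's range, and so stood far from the other 3 of their group were found in 26 of 435 groups of 4, where about 21.8 would be expected by chance, so the following are values only. N replicate 2 stood apart for Sel1l (383 CPM), Edem1 (363 CPM), Dnajc3 (255 CPM), Ldha (834 CPM), Lfng (31.1 CPM), Anxa3 (39.6 CPM) and mt-Co1 (2320 CPM), and for the respiratory chain (0.462% of counts) and mitochondrially encoded (0.813% of counts) lists. More of these values fell in this library than in any other. It also had the lowest acinar share (10.5%) and the highest erythroid share (23%) of the N libraries. The number expected by chance is over all libraries, so it does not speak to this one. A replicate 4 stood apart for its total count (25.9 M), Hbb-bs (106 CPM), Hba-a1 (86.2 CPM), the erythroid list (0.034% of counts) and Rpl7 (196 CPM). A replicate 3 was low for Notch3 (6.08 CPM) and Heyl (7.19 CPM), A replicate 2 for Kcnj11 (45 CPM), and N replicate 3 for Notch3 (29.3 CPM). B replicate 2 stood apart for Pdgfra (5.52 CPM), Cacna1h (3.08 CPM) and Ins1 (371 CPM), and B replicate 4 for its total count (16.2 M) and Notch1 (51.5 CPM). N replicate 1 stood apart for Ghrl (11.8 CPM) and the channel list (0.0379% of counts), and N replicate 4 for Cacna1h (12.6 CPM).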

How the results depend on the processing

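The fits without the A and B libraries numbered 3 and with library totals alone (no factors) were chosen after the data were seen. A fold change over 2 tested directly left 404 genes for B against A, 1566 for A against N and 4484 for B against N, since it asks for more. An estimated correlation left 0, 3 and 0 lists called; the cause was not tested. Over leave-one-out fits the genes called were 1506 to 2840 for B against A, with 1506 without B replicate 1 and 1523 without A replicate 2, and the genes changed at both steps 979 to 1676, with 979 without A replicate 2, 1012 without A replicate 1 and 1031 without B replicate 1; the cause was not tested. The acinar difference was -10.9 to -8.34 points for A against N and -13.3 to -10.8 for B against N. It lost its call without each A replicate and without B replicate 4 in turn (exact permutation p of 0.0571). It kept its call without each N replicate in turn (exact permutation p of 0.0286). The number of samples alone therefore does not account for the loss, and the cause was not tested. Without the libraries numbered 3 the acinar difference for A against N was -9.23 and the Gcg difference for B against A 2.48 points. Both lost their call (exact permutation p of 0.0571 and 0.1) in fits that held fewer samples. For Gcg, 0.1 is the smallest p that the remaining libraries allow, so its call could not have been kept. The Gcg difference itself was 2.44 points with all libraries. Other shares kept direction and side on the mm10 table and with the other denominators. Gene and list counts stayed within 1.5 times under RLE, upper quartile, both filters and the mm10 table, gene counts also under DESeq2 and with only the 2 groups compared, and both under the replicate block, which gave 2787, 8267 and 10652 genes and 15, 18 and 17 lists, and which among the 154 gene values and 72 list values compared ended no call and newly called Neurog3 and Epb42 lower in B than in A. With no factors 2323, 9629 and 11670 genes, 15, 15 and 15 lists and 1117 genes changed at both steps were called, and against N the median of all genes moved by 0.57 (A) and 0.54 (B). That ended the calls of the beta (adjusted p = 0.15), other hormone (0.176) and unfolded protein (0.209) lists for A against N and of the cell cycle (0.186), progenitor (0.0896) and glycolysis (0.132) lists for B against N; the cause was not tested. For B against N the progenitor list also lost its call with the stricter filter (0.0557) and without the libraries numbered 3 (0.0559), as did glycolysis (0.0617) and, for B against A, mitochondrially encoded genes (0.0637) without those libraries. Fry did not call granule (0.0605) and mitochondrially encoded genes (0.386) for B against A or ductal genes (0.0583) for A against N. Glycolysis gained a call for A against N with the stricter filter (0.0418), no filter (0.0497) and fry (0.02) and for B against A with no filter (0.0152), Schwann and neural genes for B against A with no filter (0.0442) and for B against N with no factors (0.0359), and guidance (0.0117) and other hormone genes (2.66e-07) for B against N with fry. Of 140 called gene values 127 kept side and direction under every alternative, 0 reversed, and 13 lost a call under at least 1, among them Aldoc, Creld2, Dnajb1, Dnajc3, Sdf2l1, Sox4 and Zg16 for B against A, mt-Co1, Cox5a and Notch1 for A against N, and Hspa5 and Notch1 for B against N. With no factors the medians of 3 called lists turned, unfolded protein for A against N (0.15) and cell cycle (0.06) and glycolysis (0.03) for B against N. The other values that reversed were not called. For lists, the direction that reversed was that of the camera or fry test. The medians printed are those of the edgeR fit, so they need not change sign, and those given with fry are the main-fit medians. Neurog3 for A against N was 0.02 with only the 2 groups compared, 0.59 with no factors and -0.52 to 0.33 over leave-one-out fits, and Notch1 for B against A -0.04 to 0.34. List medians for B against A were, for dissociation stress, 0.03 with the stricter filter, 0.04 with fry, 0.01 with no filter and with no factors, 0.02 with the replicate block, -0.01 with upper quartile factors and -0.11 to 0.1 over leave-one-out fits; for endocrine progenitors 0.05 with fry and 0 to 0.15; for channels 0.13 without the libraries numbered 3 and 0.02 to 0.12; and for ribosomal proteins -0.04 without those libraries and -0.13 to 0.01. Medians for A against N were -0.43 (guidance) and -0.68 (Schwann and neural) with fry and, for the respiratory chain, 0.47 with no factors and -0.16 to 0.01, and for B against N -1.71 (Schwann and neural) with fry, -0.18 with no filter and 0.41 with no factors for mitochondrially encoded genes and -0.26 to 0.2 over leave-one-out fits. In simulation, where 16665 of 16865 genes were unchanged for B against A, changes of 0.5 on the log2 scale were mostly missed. More genes were called in the data, where changes near that size could pass, such as Mcm7 at 0.55 for B against A. The simulated shares therefore need not hold for the data.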

Other observations

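The genes named in this part were chosen after their values were seen. Of 7 genes for plasma proteins looked at, 5 were called higher in B than in A, and no list of such genes was tested. Fgb, a fibrinogen chain, stood at 0.142 ± 0.0894 CPM in N, 7.15 ± 4.66 CPM in A and 46.6 ± 12.7 CPM in B (log2 change from A to B 2.7, SE 0.45, edgeR adjusted p = 0.00201, n = 4). Cpb2, a plasma carboxypeptidase, stood at 4.77 ± 2.49 CPM in A and 29.5 ± 13.4 CPM in B, and Serpind1, heparin cofactor, at 6.25 ± 2.35 and 26.3 ± 2.51 CPM. Serpina1b stood at 15.1 ± 6.52 and 40 ± 19.6 CPM, with copies that can share reads. Afp, alpha-fetoprotein, stood at 2.97 ± 1.27 CPM in A and 8.57 ± 1.45 CPM in B. Alb, the albumin gene, at 2.94 ± 0.767 CPM in A and 4.93 ± 1.49 CPM in B, was not called (edgeR adjusted p = 0.172). Apoa1, an apolipoprotein, at 5.34 ± 9.88 and 7.09 ± 2.69 CPM, was not called either (edgeR adjusted p = 0.894).

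Npy, which encodes neuropeptide Y, was highest in A, at 64.9 ± 41.5 CPM against 19 ± 8.44 CPM in N and 8.26 ± 6.11 CPM in B. Sct, which encodes secretin, stood at 0.64 ± 0.286 CPM in N, 7.45 ± 1.68 CPM in A and 20.9 ± 5.57 CPM in B. Ins2 stood at 3600 ± 1420 CPM in N, 5350 ± 3830 CPM in A and 861 ± 194 CPM in B, so the A mean lay above the N mean, within the spread of the A libraries (edgeR adjusted p = 0.306, A against N). Nkx6-2, a homeobox gene, stood at 1.57 ± 0.788 CPM in N, 0.615 ± 0.308 CPM in A and 8.61 ± 1.52 CPM in B.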
